A study of Mus musculus with 17 samples.

How the data were processed

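RNA of 17 mouse mammary gland libraries was sequenced from sorted macrophages, cultured macrophages and P4 basal cells, in 12 groups of 1 or 2 libraries. Per the labels, total RNA was purified on RNeasy columns, ribosomal RNA was removed with QIAseq FastSelect reagents and libraries were made with PrepX chemistry on an Apollo 324 instrument. The submitters' notes name STAR 2.7.8a, Partek and the human build hg38, although the deposited symbols and coordinates are mouse; the counting step and its settings are not stated. Start positions matched GENCODE M21 on GRCm38 for 99.5% of the genes compared in the knockout-experiment and CXCR4 tables, 2.66% in the culture table and 41.8% in the P4 table, so no coordinates are given for the last 2.

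The deposited values of the 3 macrophage tables are log2 values, log2(CPM + 0.0001), given for 19782, 17130 and 18909 genes. Their unit was read from the values: 2 to the power of each value, less 0.0001, gave multiples of 1 step, taken as 1 read, for 74.1% to 90.1% of values up to 50 reads (tolerance 0.05 reads); the rest were fractional, so the tables hold no counts. Library depth was the sum of CPM divided by that step. The deposited P4 table holds FPKM in the layout of a Cufflinks tracking file, with 27040 entries and unknown depth. The plan had foreseen counts; the fallback written for normalized values was used throughout. Of entries sharing a symbol, the first with the highest level was kept, which dropped 91 in the culture and 27 in the P4 table, and 429 P4 entries had no gene name.

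Knockout changes were fitted with limma 3.58.1 in R 4.3.3 on log2(CPM + 1) over the 8 libraries, with 4 group means, no block, empirical Bayes moderation with a mean-variance trend, and genes of at least 1 CPM in at least 2 libraries. Contrasts were knockout minus control in each Cre line and the difference between them. The same model, with 2 groups, was fitted to the 3 libraries sorted by CXCR4. A p was adjusted by Benjamini-Hochberg over all genes tested, and passed under 0.05; tests are two-sided and intervals cover 95%. The pseudocount of 1 shrinks log2 changes of genes with low levels. The prior carried 97.3 degrees of freedom beside 4 residual in the knockout fit, and was infinite beside 1 residual in the CXCR4 fit. Detection was tested on simulated data, drawn from a normal distribution around each gene's mean with its fitted spread, to which known changes were added. That spread was equal in all libraries, unlike in the data. For K8-Cre control against Cxcl12 knockout, the SD of log2 differences was 2.44 in repeat 1 and 0.65 in repeat 2.

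Gene lists, 36 in number with 782 memberships, were fixed before the data were examined; they cover chemokine and growth factor signalling, macrophage states, metabolism, mammary and other cell types, and RNA quality. Of the memberships, 731 matched genes of the knockout table, 713 of the CXCR4 table, 707 of the culture table and 756 of the P4 table. Between 35 and 36 lists were tested per comparison with camera (limma), preset correlation 0.01, adjusted over the lists, beside camera with an estimated correlation and fry. A camera call says that the list moved against other genes. With an estimated correlation, camera refers its statistic to the residual degrees of freedom, 4 in the knockout fit and 1 in the CXCR4 fit. With so few, a list needs a very large statistic to pass. A call that ended there thus does not show that correlation between genes had made it. The standard error of a list median was taken over the genes of the list. Those genes are not independent, so it does not measure the spread between samples. No list passed in any comparison with the estimated correlation or with fry's test of 1 direction, whose lowest adjusted p was 0.0524; fry's test of change in either direction passed for 5 lists of the CXCR4 sort (lowest adjusted p = 0.0335) and for none of the knockout comparisons (lowest 0.0663). Some genes are in more than 1 list, and the genes of the CXCR4-positive set were chosen on other libraries than those of the knockouts. A p adjusted over a list alone was adjusted within that list and not across lists, so some such passes can arise by chance.

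Culture and P4 libraries have no replicates and were compared as log2 ratios, with a prior of 2 reads at the mean depth (0.0993 CPM) or of 1 FPKM. Counts over all genes and named genes needed at least 10 CPM or FPKM in the higher library. Lists and the random lists took genes of at least 1 CPM or FPKM there. List medians and counts of list members can thus include genes near the floor. A list was described by its median, set against 10000 random lists of equal size drawn within 20 bins of mean level. Genes of a list can move together within a library, while random lists are drawn gene by gene. An extreme percentile can thus arise between 2 libraries without an effect of treatment or genotype. Percentiles are descriptive, are not p-values and were not adjusted for the number of lists. Levels and floors of 3 reads cover counting error only, since reads without molecular identifiers are not independent molecules. Correlations across genes are descriptive.

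Genes were named by rule: always Cxcr4 and Cxcl12; where tested, up to 10 highest and 10 lowest changes that passed, at 10 CPM or more in the higher group and without overlap of libraries; where fewer than 5 passed in a direction, the 5 smallest p, said not to pass; up to 4 members of a list described; and for single libraries the 10 highest and 10 lowest ratios. Predicted genes without a usual symbol were counted and not named, and some genes that the rule selects are not reported here. Adgre1, Lyz1, Csf1r, Itgam, Ptprc and keratin genes were named after their values were seen.

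Alternatives covered quantile and median-ratio scaling, the trend, the pseudocount, the filters, the threshold, leaving out each library, a replicate block, library weights, voom weights, sharing of the spread and, for single libraries, the prior and the minimum level; their effects are given with the closing observations. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.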

Results

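RNA was sequenced from 17 libraries of mouse mammary gland cells in 12 groups. Macrophages sorted on F4/80 and CD11b from virgin mice made up 8 libraries of the knockout experiments, with 2 in each of 4 groups: LysM-Cre control, LysM-Cre Cxcr4 knockout, K8-Cre control and K8-Cre Cxcl12 knockout. LysM-Cre is active in myeloid cells, and K8-Cre in luminal epithelial cells. The labels name the controls wild type control mice of each Cre line. CXCR4 is the receptor of the chemokine CXCL12. A further 3 libraries held macrophages sorted by surface CXCR4, 2 positive and 1 negative. Cultured macrophages gave 4 libraries, 1 each for untreated cells, recombinant CXCL12, the AKT inhibitor GSK690693 and both together. The last 2 libraries, 1 from a K8-Cre control and 1 from a K8-Cre Cxcl12 knockout, held the P4 population, basal cells enriched for mammary stem cells.

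Depth differed between libraries. The knockout-experiment macrophages had 8.60 to 37.2 M reads, the CXCR4 sort 23.2 to 28.8 M reads and the cultured cells 14.3 to 29.04 M reads, as read from the smallest step between values. A count of 3 reads corresponded to between 0.0806 and 0.349 CPM, reads normalised to library depth, in these libraries. The depth of the P4 libraries is unknown. Among the knockout-experiment libraries, K8-Cre control 1 had 37.1% and LysM-Cre control 1 had 30.6% of the listed genes at 0, against 8.27% in K8-Cre Cxcl12 knockout 2. Small noncoding RNA took 2.97% to 6.71% of the reads in the 4 libraries numbered repeat 1 and 15.2% to 19.3% in the 4 numbered repeat 2. Because of this split, knockout changes are given below also within repeat 1 and within repeat 2, for some genes as ranges. The labels do not state whether samples of a group came from separate mice, so each p concerns samples and not mice. The spread behind it came mostly from the trend over genes of like level, not from the gene's own samples. The knockout fit had 97.3 prior against 4 residual degrees of freedom, and in the CXCR4 fit the spread came wholly from that trend.

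The first comparison asked what loss of Cxcr4 in myeloid cells did to mammary macrophages. Lyz2, which encodes the macrophage lysozyme, fell to a mean of 59.6 ± 11.1 CPM (SD, n = 2) in the knockout from 6503 ± 5265 CPM (SD, n = 2) in the control. Its log2 change was -6.47 (SE 0.40, 95% interval -7.26 to -5.68, adjusted p = 1.03e-25), with -7.22 in repeat 1 and -5.72 in repeat 2. In LysM-Cre mice the Cre insertion sits in Lyz2 itself, and the labels do not give its genotype. The labels therefore do not tell an effect of the insertion from one of Cxcr4 loss on Lyz2, which the closing observations weigh. Cxcr4, the targeted gene, had 232 and 140 CPM in the knockout libraries against 819 and 318 CPM in the controls. Its log2 change of -1.49 (SE 0.49, 95% interval -2.46 to -0.53) was -1.81 in repeat 1 and -1.18 in repeat 2. That change did not pass over all genes (adjusted p = 1) but passed when adjusted over the list alone, that of the CXCL12 and CXCR4 axis (adjusted p = 0.0272, 1 of 10 members). Leaving out each of the 8 libraries in turn gave log2 changes from -2.17 to -0.81; it passed over all genes only without LysM-Cre control 2 (-2.17, adjusted p = 0.0145), and stood at -0.81 (adjusted p = 1) without LysM-Cre control 1. Cxcl12 stood at a log2 change of -0.82 (SE 0.94, adjusted p = 1), with opposite signs in the repeats (-1.80 in repeat 1, 0.16 in repeat 2).

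In the annotation of build GRCm38, Lyz2 (ENSMUSG00000069516) lies on chromosome 10 from 117277331 to 117282321, Cxcr4 (ENSMUSG00000045382) on chromosome 1 from 128588199 to 128592293, and Cxcl12 (ENSMUSG00000061353) on chromosome 6 from 117168535 to 117181367. All 3 are protein-coding genes.

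**Figure D1:**
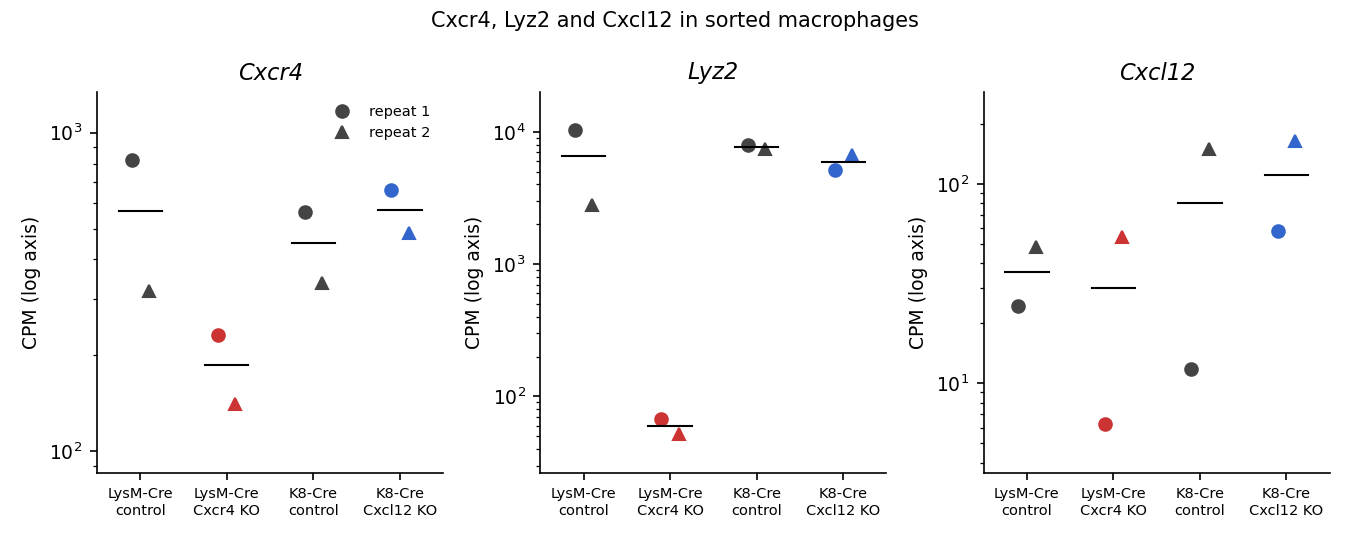
Levels of Cxcr4, Lyz2 and Cxcl12 in CPM on a log axis for the 8 sorted macrophage libraries of the knockout experiments; circles are repeat 1, triangles repeat 2 and lines the mean of each group. Lyz2 lies at 67.4 and 51.7 CPM in the Cxcr4 knockout libraries and at 2780 CPM or above in the other 6.

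Lyz2 was the 1 gene of 17275 tested that passed with limma, and 575 genes had an unadjusted p under 0.05, of which 374 were higher and 201 lower. Without the mean-variance trend the Lyz2 call also ended (adjusted p = 1), while its log2 change stayed at -6.47. The count was 17 without LysM-Cre control 1, 150 without LysM-Cre control 2, 19 without LysM-Cre Cxcr4 knockout 2, 4 without K8-Cre Cxcl12 knockout 1 and 3 without K8-Cre Cxcl12 knockout 2. Genes next in rank that did not pass were higher for Ifi204, an interferon-inducible DNA sensor (log2 change 3.54), Virma (3.34), Armcx3 (4.31), Gvin1 (2.49) and Pprc1 (4.39). Lower, also without passing, were Rpl9-ps4 (-2.44), Rps24-ps3 (-2.54), Prpf19 (-3.15), Il15ra (-3.25) and Ube3a (-1.87). Most of these rested on repeat 1. The higher genes stood at 5.45 to 7.15 there and at -0.47 to 2.98 in repeat 2, with Ifi204 (-0.07) and Gvin1 (-0.47) below 0, Virma at 0.13, Pprc1 at 2.52 and Armcx3 at 2.98; the lower ones stood at -6.12 (Il15ra) to -3.43 (Ube3a) in repeat 1 and at -0.61 (Prpf19) to -0.31 (Ube3a) in repeat 2. Rpl9-ps4 and Rps24-ps3 are pseudogenes of ribosomal protein genes, so their reads may belong to other copies. In data simulated with an equal spread in all libraries, 4.48% of 67 genes given a log2 change of 2 were recovered. At a change of 4 it was 34.8% of 66. The real libraries differed in spread, so these rates are a rough guide.

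Among 36 gene lists, 2 passed for the Cxcr4 knockout with the preset correlation, and neither held a gene that passed singly. B cell genes, markers of a lineage that the macrophage gate would remove, were lower against other genes (median log2 change -0.95, 5 of 15 above 0, adjusted p = 0.0119), with medians of -1.61 in repeat 1 and -0.46 in repeat 2. Examples are Ighd (-2.56; -5.64 in repeat 1, 0.52 in repeat 2), Cr2 (-2.90; -5.11 and -0.70) and Cd79b (-3.06; -5.37 and -0.76). Immediate early and heat shock genes linked to tissue dissociation were lower too (median -0.28, 8 of 28 above 0, adjusted p = 0.00711), at -0.55 in repeat 1 and 0.03 in repeat 2; Junb stood at -0.81 (-1.22 and -0.40) and Hspa1b at -0.75 (-1.61 and 0.11). Both calls ended with an estimated correlation (adjusted p = 0.884 for each), with quantile normalization, and without LysM-Cre control 1 or LysM-Cre Cxcr4 knockout 2, while 6 lists passed without LysM-Cre control 2 and 13 without LysM-Cre Cxcr4 knockout 1. Adjusted over the list alone, 3 genes that did not pass over all genes were higher, each in 1 list: Ifi204 of the interferon response (3.54, adjusted p = 0.00193), Ly6c2 of the monocytes (2.25, adjusted p = 0.0163; 3.91 in repeat 1, 0.60 in repeat 2) and Fcna, a ficolin of resident macrophages (3.95, adjusted p = 0.0243; 7.47 in repeat 1, 0.43 in repeat 2). That adjustment was made within each list and not across the 36 lists. The lists of Wnt ligands (median 0.16, adjusted p = 0.806) and of Notch pathway genes (median -0.09, adjusted p = 0.473) did not pass.

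The second comparison asked what deletion of Cxcl12 in luminal cells did to macrophages of the same glands. Genes of general macrophage identity were lower against other genes in the knockout, with a median log2 change of -0.39 and 4 of 20 members above 0, while the median of all genes tested was 0.36. The complement genes C1qa (-1.24), C1qb (-1.11) and C1qc (-1.60), which opsonise dying cells, were among its lowest members, and none passed singly; they were lower in both repeats, at -1.60, -1.70 and -2.70 in repeat 1 and at -0.87, -0.52 and -0.51 in repeat 2. The median was -0.63 in repeat 1 and -0.30 in repeat 2. The list passed with the preset correlation (adjusted p = 2.68e-05) and not with an estimated correlation (adjusted p = 0.629). Spi1, the PU.1 transcription factor of myeloid cells, stood at 2.58 without passing (4.71 in repeat 1, 0.44 in repeat 2).

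A further 7 lists were lower against other genes with the preset correlation and lost their calls with an estimated one, where the lowest adjusted p over all lists was 0.629. Complement and efferocytosis genes had a median of -0.19 (adjusted p = 0.00431; -0.54 in repeat 1, -0.14 in repeat 2). Resident stromal macrophage genes stood at -0.20 (adjusted p = 0.0084; -0.57 and -0.35), with Cd209f at -1.04 and Gas6 at -1.21. Alternative activation genes stood at -0.28 (adjusted p = 0.0084; -0.46 and -0.14), with Clec10a at -0.72 and Retnla at -0.39. CX3CR1 ductal macrophage genes stood at -0.30 (adjusted p = 0.0112; -0.53 and -0.25), with Apoe at -0.83 and P2ry12 at -1.70. Dissociation stress genes stood at -0.23 (adjusted p = 0.00952; -0.25 and -0.19). Lysosome genes stood at -0.12 (adjusted p = 0.00431) with 0.05 in repeat 1 and -0.06 in repeat 2, and mitochondrially encoded genes at -0.14 (adjusted p = 0.013) with 0.40 and -0.64. Cd209f, Gas6, Clec10a, Retnla, Apoe and P2ry12 were below 0 in both repeats. In none of the 36 lists did a gene pass adjusted over the list alone.

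No gene of 17275 passed for the Cxcl12 knockout with limma, while 491 had an unadjusted p under 0.05, 415 higher and 76 lower. In data simulated with an equal spread in all libraries, which the real ones did not have, 4.48% of 67 genes given a log2 change of 2 were recovered. At a change of 4 it was 19.7% of 66. The lack of calls thus does not show a lack of change. Limma with voom weights gave 7 genes. Cxcr4 stood at a log2 change of 0.37 (SE 0.49; 0.23 in repeat 1, 0.52 in repeat 2) and Cxcl12 at 1.18 (SE 0.94; 2.22 and 0.13). The smallest p among genes that were higher belonged to Rpl10-ps1 (3.34), Tomm22 (3.34), Tmcc1 (2.93), Atp6v0a2 (2.996) and Atad1 (2.80), and among genes that were lower to Cd300ld3 (-3.63), Mir3535 (-4.65), Rpl17-ps9 (-2.55), Gpld1 (-3.06) and C1qc (-1.60). Those named as higher rested on repeat 1, from 5.39 (Atad1) to 6.71 (Rpl10-ps1), against -0.05 (Tmcc1) to 0.60 (Tomm22) in repeat 2. Those named as lower were below 0 in both, from -6.48 (Mir3535) to -0.85 (Rpl17-ps9) in repeat 1 and from -4.25 (Rpl17-ps9) to -0.51 (C1qc) in repeat 2. Quantile normalization moved the median of all genes from 0.36 to 0.02 here, from 0.14 to 0.01 for the Cxcr4 knockout and from -0.20 to -0.09 for the CXCR4 sort; it left 1 of the 8 lists, general macrophage identity. Leaving out K8-Cre control 2 gave 151 genes and left 1 of the 8 lists. Of the 8, 4 also passed without K8-Cre control 1, 2 without K8-Cre Cxcl12 knockout 1 and 6 without K8-Cre Cxcl12 knockout 2, where 7 genes passed.

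The knockouts were then compared with each other. The change of Lyz2 differed between them by -6.08 on the log2 scale (SE 0.56, adjusted p = 2.88e-14), and it was the 1 gene of 17275 that passed, with 428 at an unadjusted p under 0.05. The count was 30 without LysM-Cre control 2, and between 1 and 5 without any other library; without the mean-variance trend Lyz2 did not pass here either (adjusted p = 1.00). Lyz2 in the Cxcl12 knockout had a mean of 5889 ± 1117 CPM (SD, n = 2) against 7677 ± 346 CPM (SD, n = 2) in its control. In the LysM-Cre line the labels do not tell the Cre insertion in Lyz2 from the loss of Cxcr4. For Cxcr4 the difference was -1.87 (SE 0.69, adjusted p = 1). Adjusted over the list alone, Ifi204 (4.13, adjusted p = 0.0261), Fcna (5.37, adjusted p = 0.0364) and Sirpb1c (-5.47, adjusted p = 0.00635) also passed. This adjustment does not cover the number of lists. In the Cxcr4 knockout the change of Ifi204 was 7.15 in repeat 1 and -0.07 in repeat 2. All 13 mitochondrially encoded genes had a positive difference (median 0.41, adjusted p = 0.0271 with the preset and 0.940 with an estimated correlation). Its medians were 0.26 for the Cxcr4 and 0.40 for the Cxcl12 knockout in repeat 1, and 0.28 and -0.64 in repeat 2, so the positive difference came from repeat 2. This list did not pass without LysM-Cre control 2, LysM-Cre Cxcr4 knockout 1, K8-Cre control 1, K8-Cre control 2 or K8-Cre Cxcl12 knockout 2, each left out alone, nor with quantile or median-ratio scaling. Across the 17275 genes, which are not independent replicates, the changes of both knockouts had a Pearson r of 0.016 and a Spearman rho of 0.018; r was 0.007 in repeat 1 and -0.007 in repeat 2.

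The CXCR4 sort compared 2 CXCR4-positive libraries with 1 CXCR4-negative library. The negative group has no replicate, so every call of a gene here and below assumes that it varies like the positive pair. All of these calls ended without the mean-variance trend, and also without the filter on low values. At 10 CPM or more in the higher library, the positive libraries differed at least 2-fold from the negative one in 33.8% and 37.1% of genes and from each other in 16.8%, while replicates within groups of the knockout experiments differed in 27.9% to 59.6%. Cxcr4 mRNA itself was 632 and 875 CPM in the positive libraries and 772 CPM in the negative one (log2 difference -0.05, SE 0.33, adjusted p = 0.958; 0.047 with median-ratio scaling). Genes of resident stromal macrophages were higher in CXCR4-positive cells: 19 of 20 passed, 19 also adjusted over the list alone, with a median log2 difference of 4.18. Cd209f, a C-type lectin, averaged 331 ± 62.8 CPM (SD, n = 2) against 1.10 CPM, and Folr2, the folate receptor of resident macrophages, 181 ± 38.5 CPM (SD, n = 2) against 2.41 CPM. Among complement and efferocytosis genes 19 of 23 were higher (20 adjusted over the list alone, median 3.49), with C1qc at 485 ± 69.5 CPM (SD, n = 2) against 4.57 CPM. Genes of monocytes, of dendritic cells and of class II antigen presentation were lower. All of these list calls rest on the preset correlation and ended with an estimated one, with an adjusted p of 0.453 for the stromal, complement and monocyte lists, 0.583 for dendritic cells and 0.565 for class II. The latter test had 1 residual degree of freedom. For the stromal list the estimated correlation, -0.0105, lay under the preset 0.01, yet p from camera went from 5.68e-106 to 0.0265. The lost calls thus do not show correlation between genes, and they do not support the preset calls either.

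The 10 genes with the highest differences were Cd209f (7.29), Ednrb (6.94), Cbr2 (6.65), C1qc (6.44), Ms4a7 (6.29), Cd209g (6.20), C6 (6.08), Stab1 (6.07), Ccl7 (5.94) and Pf4 (5.77). The lowest were F5 (-6.38), Rab44 (-5.88), Flt3 (-5.16), Scn3a (-5.08), Adam11 (-4.64), Bcl11a (-4.63), Syne1 (-4.60), Dscam (-4.59), Rab11fip4 (-4.50) and Mcemp1 (-4.47). Flt3, the receptor that dendritic cell precursors depend on, had 18.1 and 0.441 CPM in the positive libraries and 187 CPM in the negative one. Coagulation factor gene F5 had 5.45 and 1.40 CPM against 327 CPM. Cxcl12 stood at 1.22 and did not pass (adjusted p = 0.0940).

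**Figure D2:**
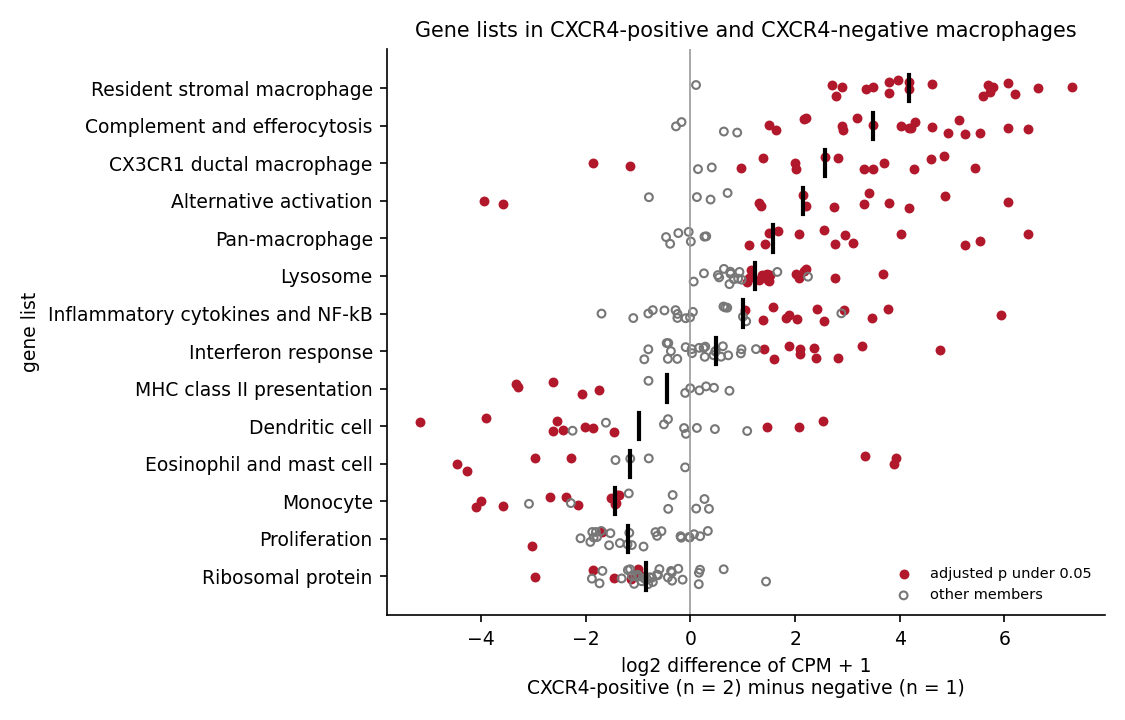
Each point is 1 gene of a list, placed by its log2 difference of CPM + 1 between 2 CXCR4-positive libraries and 1 CXCR4-negative library; filled points have an adjusted p under 0.05 over all genes and black bars are list medians. The median is 4.18 for resident stromal macrophage genes and -1.44 for monocyte genes.

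Further lists were higher in CXCR4-positive macrophages with the preset correlation, and none of them passed with an estimated correlation (adjusted p from 0.453 to 0.457). General macrophage identity had 13 of 20 genes higher (13 adjusted over the list alone, median 1.59), with Csf1r, the receptor of the macrophage growth factor CSF1, at 1.67, while Itgam, which encodes the sort marker CD11b, stood at 0.01 without passing. CX3CR1 ductal macrophage genes had 13 higher and 2 lower of 17 (median 2.56), with Apoe at 4.59, Mmp13 at 5.43, Vcam1 at 3.69 and Axl at 3.49. Alternative activation genes had 11 higher and 2 lower of 17 (median 2.15), with Mrc1, the mannose receptor, at 4.17, Cd163 at 3.79 and Il10 at 4.86. Lysosome genes had 16 of 30 higher (23 adjusted over the list alone, median 1.24), Ctsb at 2.76. Inflammatory cytokine genes had 12 of 29 higher (14 higher and 1 lower adjusted over the list alone, median 1.00), with the monocyte attractants Ccl7 at 5.94 and Ccl2 at 3.78. Interferon response genes had 10 of 33 higher (11 adjusted over the list alone, median 0.48), with Oasl1 at 4.78 and Ifit1 at 3.28. Among secreted growth factors 7 of 27 were higher and 1 was lower (9 and 1 adjusted over the list alone, median 1.06), with Igf1 at 5.06, Gdf15 at 3.12, Grn at 2.64 and Pdgfc at 4.60. Matrix remodelling genes had 8 higher and 3 lower of 22 (median 0.97), Plau at 3.89 and Thbs1 at -2.31.

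Markers of other cells were higher as well in the positive libraries: 4 of 16 fibroblast genes (median 0.97; Col1a1 at 1.99, Col3a1 at 1.79). The basal mammary list passed on 2 higher and 1 lower of 16 genes (median 0.35), its top members being Apoe and Itga6 (1.64), and the luminal progenitor list on 3 higher and 1 lower of 15 (median 0.94), with Cd14 at 3.10, Trf at 2.52 and Kit at -2.97; Apoe and Cd14 are also macrophage genes. With an estimated correlation these calls ended, at an adjusted p of 0.808 for the fibroblast, 0.582 for the basal and 0.808 for the luminal progenitor list.

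Lower in CXCR4-positive macrophages were 11 of 19 monocyte genes (13 adjusted over the list alone, median -1.44), with Ace at -3.99, Chil3 at -3.58, Plac8 at -2.69 and S100a4 at -2.38. This list call and the next 4 ended with an estimated correlation (adjusted p from 0.453 to 0.777). Class II presentation genes had 5 of 12 lower (6 lower and 1 higher adjusted over the list alone, median -0.45), with H2-DMb2 at -3.29 and Ciita, the class II transactivator, at -2.07. Dendritic cell genes had 8 lower and 3 higher of 20 (median -0.98), with Cd209a at -2.42 and Dpp4 at -2.63, while Siglech, a plasmacytoid marker, stood at 2.54. Ribosomal protein genes had 6 of 38 lower (7 adjusted over the list alone, median -0.86) and proliferation genes 2 of 26 (5 adjusted over the list alone, median -1.18), Ube2c at -3.02. Eosinophil and mast cell genes did not pass as a list (adjusted p = 0.0758), with 4 lower, among them Siglecf (-4.46) and Ccr3 (-4.26), and 3 higher of 11. The lists of Wnt ligands (adjusted p = 0.459) and Notch pathway genes (adjusted p = 0.764) did not pass, though Wnt11 was lower (-3.84) and Notch1 higher (1.20). Their medians, 0.32 and -0.39, had the opposite sign to the direction of the test. Single genes of all these lists passed only with both the mean-variance trend and the filter on low values, against 1 negative library.

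In all, 1219 of 14411 genes differed with limma, 729 higher and 490 lower in CXCR4-positive cells; with voom weights the split was 457 and 571. The spread came from the 2 positive libraries alone, with 1 residual degree of freedom, and the single negative library was assumed to vary like them. No gene passed without the mean-variance trend or without the filter on low values, and 81 did when the spread was shared with the knockout-experiment libraries. Adjusted p of the 18 lists that passed ranged up to 0.0270 with the preset correlation, the largest being that of the luminal progenitor list, and from 0.453 upward with an estimated correlation.

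The genes that set CXCR4-positive macrophages apart were looked up in the knockouts. The 729 higher genes had a median change of 0.08 above that of all genes in the Cxcr4 knockout and -0.25 in the Cxcl12 knockout, and the 490 lower genes -0.05 and -0.20; with quantile normalization the higher genes stood at 0.16 and -0.01. None of these 4 sets passed (adjusted p = 0.236, 0.236, 0.706 and 0.706). With the 100 higher genes of smallest p, the set stood at 0.22 in the Cxcr4 knockout (adjusted p = 0.00632) and at -0.43 in the Cxcl12 knockout (adjusted p = 0.00283), and both calls ended with an estimated correlation (adjusted p = 0.781).

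Cultured macrophages showed lower interferon response genes with the AKT inhibitor, both without and with CXCL12. Lists in culture held genes of at least 1 CPM in the higher library. Without CXCL12, 19 of 32 such interferon response genes were at least 2-fold lower than in untreated cells and none 2-fold higher, with a median log2 ratio of -1.24. Isg15, a ubiquitin-like modifier induced by interferon, had 9.64 CPM against 55.6 CPM, Mx1 15.4 against 87.3 CPM, Oas1a 7.83 against 49.7 CPM and Zbp1 2.86 against 20.2 CPM. With CXCL12, 22 of 33 were at least 2-fold lower than with CXCL12 alone, with a median of -1.33. Ifi44 had 4.802 against 62.0 CPM, Mx2 8.48 against 72.4 CPM and Xaf1 2.93 against 64.9 CPM. Their log2 ratios without CXCL12 were -0.67, -1.08 and -0.17. In the library with both treatments 413 genes were under 1 CPM and above 10 CPM in every other culture library. The others had between 10 and 58 such genes each. Loss of single genes in that library thus cannot be told apart from larger falls with CXCL12. In both contrasts the median lay below those of all 10000 random lists matched on expression. Genes of a list can move together in 1 library, so this is no measure of error between samples. Of 33 genes, 14 were at least 2-fold lower in both, whereas Oas1a and Zbp1 were not lower with CXCL12 present, at 47.6 against 29.5 CPM and 23.4 against 22.9 CPM.

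**Figure D3:**
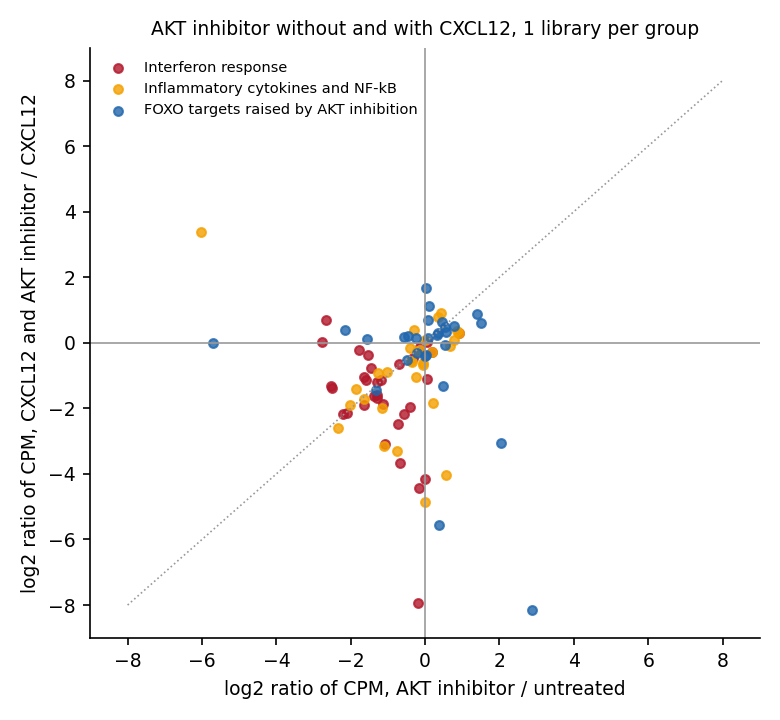
Each point is 1 gene, placed by its log2 ratio of CPM for the AKT inhibitor over untreated cells (horizontal) and for CXCL12 with inhibitor over CXCL12 alone (vertical), with 1 library per group; the dotted line marks equal ratios. Of 33 interferon response genes, 26 lie below 0 on both axes.

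Inflammatory cytokine genes had a median of -0.61 for the inhibitor in the presence of CXCL12, below all random lists, with 11 of 30 at least 2-fold lower; Ptgs2, the inducible cyclooxygenase, had 165 against 999.4 CPM. Without CXCL12 the median was -0.24 (percentile 3.81), with 9 of 29 lower, among them Ptgs2 (144 against 732 CPM), Il1a (81.3 against 333 CPM) and Ccl4 (97.0 against 351 CPM). Targets of FOXO factors, which AKT normally holds out of the nucleus, had a median of 0.09 without CXCL12 (percentile 72.0) and 0.18 with it (percentile 80.5). Mammary stem cell genes had a median of -1.14 for the inhibitor with CXCL12 (percentile 1.715) and 0.21 without it (percentile 77.4). The first median rests on the library with both treatments, where loss of single genes cannot be told apart. The inhibitor without CXCL12 also came with a median of 0.47 for glycolysis and hypoxia genes (percentile 99.3; Gpi1 119 against 22.1 CPM), -0.71 for CX3CR1 ductal macrophage genes (percentile 0.33), -4.07 for neutrophil genes (percentile 0.18, 6 of 8 at least 2-fold lower), 0.43 for endothelial genes (percentile 99.7) and 0.44 for mitochondrially encoded genes (percentile 99.9). With CXCL12 present these medians were less extreme, at 0.28 for glycolysis and hypoxia (percentile 85.9), -0.54 for CX3CR1 ductal macrophage (percentile 6.555), -1.58 for neutrophil (percentile 59.98, 4 of 7 at least 2-fold lower and 3 higher), 0.35 for endothelial (percentile 95.02) and 0.06 for mitochondrially encoded genes (percentile 56.7).

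CXCL12 alone came with a median of 0.26 for inflammatory cytokine genes (percentile 99.97, 2 of 30 at least 2-fold higher and 2 lower), with Cxcl2, a neutrophil attractant, at 1480 against 786 CPM and Cd80 at 100.1 against 44.5 CPM. Monocyte genes had a median of 0.59 (percentile 99.9, 6 of 19 higher; S100a6 101 against 32.4 CPM), mitochondrially encoded genes 0.33 (above all 10000 random lists), ribosomal protein genes 0.45 (percentile 99.9), luminal progenitor genes 0.57 (percentile 99.4), eosinophil and mast cell genes 0.64 (percentile 99.1) and fibroblast genes -0.71 (percentile 0.52; Col1a1 25.2 against 63.2 CPM). With the inhibitor present, CXCL12 came with -1.32 for mammary stem cell genes (percentile 0.19), -0.31 for endothelial genes (percentile 1.45), -1.20 for luminal progenitor genes (percentile 2.21), -0.39 for glycolysis and hypoxia genes (percentile 2.38) and 0.03 for inflammatory cytokine genes (percentile 57.0). The medians of monocyte (-0.11, percentile 43.4), mitochondrially encoded (-0.15, percentile 6.225) and ribosomal protein genes (-0.23, percentile 38.1) then had the opposite sign, and those of fibroblast and of eosinophil and mast cell genes were -0.94 (percentile 4.95) and 0.17 (percentile 75.4). All medians with the inhibitor present rest on the library with both treatments, where loss of single genes cannot be told apart. Without the inhibitor, CXCL12 came with 0.20 for mammary stem cell (percentile 87.8), -0.19 for endothelial (percentile 4.73) and -0.14 for glycolysis and hypoxia genes (percentile 16.6). Cxcr4 had 184 CPM in untreated cells, 139 with CXCL12, 175 with the inhibitor and 379 with both; Cxcl12 had 277, 218, 282 and 443 CPM.

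The genes with the most extreme ratios in culture were mostly listed at 0 in 1 library. For CXCL12 over untreated, the 10 highest (Pcdhgb7, Vps53, Fhl5, Bcl9, Map10, Pheta1, Vcpkmt, Mthfd1, Tars2 and Tgm4) had 16.1 to 37.4 CPM and the lowest (Dnajb6-ps, Glycam1, Slfn5os, Ubox5, Tmem109, Rps18-ps5, Rpl17-ps3, Smim19 and Atl1) 16.2 to 34.1 CPM in the library where they were found. For the inhibitor over untreated, the highest (Jazf1, Rpl27, Sh2d2a, Lmcd1, Orc6, Tfeb, Gemin7, Ica1l, Cep152 and Ajuba) had 22.3 to 43.0 CPM and the lowest (Rpl9-ps4, Ssbp3, Gja5, Kctd19, Rnaset2b, Lrrc14, Sco2, Ogfod1, Dclk1 and Tctn3) 21.9 to 41.5 CPM. For both treatments over the inhibitor, the highest (Rps2-ps6, Rpl9-ps4, Jrkl, Cdk5, Pdik1l, Fgd2, Cadps2, Rab40c, Mdp1 and Mrps34) had 43.3 to 90.9 CPM and the lowest (Myo1h, Fbxo32, Ncaph2, Parg, Hps4, Rpl27, Pcif1, Abi3bp, Mrps25 and Erg) 38.8 to 96.8 CPM. For both over CXCL12, the highest (Rps2-ps6, Fdxacb1, Miip, Rpl17-ps3, Lsmem2, Mdp1, H2ac19, Gipr, Yipf1 and Adam21) had 28.4 to 88.5 CPM and the lowest (Derpc, Bcl2a1a, Hspbap1, Ilkap, Dnajb2, Mrps25, Parg, Evi2, Usp49 and Zfp992) 35.4 to 77.5 CPM.

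With 1 library per culture group there was no replicate to measure error and no p. At 10 CPM or more in the higher library, 1158 of 9678 genes were at least 2-fold higher and 1387 lower with CXCL12, and 2021 of 10158 higher and 1664 lower with the inhibitor. Both together gave 2232 higher and 2862 lower of 10408 against the inhibitor, and 2368 higher and 2431 lower of 10055 against CXCL12. At a minimum of 1 CPM the balance turned, to 3994 higher and 3652 lower with CXCL12 and 4010 higher and 4286 lower with the inhibitor. Both together then gave 2872 higher and 5745 lower against the inhibitor, and 2934 higher and 6561 lower against CXCL12. The library with both treatments had 31.0% of genes at 0, against 12.4% to 19.7% in the other 3. Replicate libraries of the knockout experiments differed at least 2-fold in 27.9% to 59.6% of genes at this level and the CXCR4-positive pair in 16.8%, against 26.3% for CXCL12 over untreated, 36.3% for the inhibitor over untreated, 48.9% for both over the inhibitor and 47.7% for both over CXCL12. The shares between replicates were taken with 1 CPM added and those in culture with 0.0993 CPM added. The larger value shrinks ratios more, so the shares are not fully alike. Across 8628 genes the CXCL12 ratios without and with inhibitor had a Pearson r of 0.015, and 489 genes were 2-fold apart in opposite directions against 219 higher and 300 lower in both. The inhibitor's ratios without and with CXCL12 had r of 0.049, and 0.23 among genes of at least 50 CPM.

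In the P4 sort the Cxcl12 knockout library had higher inflammatory and stromal transcripts than the control library. Whether basal cells or other cells in the sort held these transcripts was not tested. Inflammatory cytokine genes had a median log2 ratio of 0.96, above those of all 10000 random lists, with 10 of 23 at least 2-fold higher and 1 lower. The neutrophil attractant Cxcl1 had 377 against 126 fragments per kilobase, scaled for depth (FPKM), Ccl7 58.3 against 17.5 FPKM and Ptgs2 52.4 against 17.4 FPKM. Fibroblast genes had a median of 0.80 (also above all random lists, 6 of 18 higher; Col1a1 107 against 46.6 FPKM), and Ptprc, the pan-leukocyte gene that the lineage gate should exclude, had 4.26 against 0.604 FPKM. Interferon response genes had a median of 0.84 (percentile 99.8), monocyte genes 0.74 (percentile 99.9; S100a4 34.8 against 1.91 FPKM), complement genes 0.54 (percentile 99.8; C3 328 against 164 FPKM) and adipocyte genes 1.17 (percentile 99.9; Fabp4 25.6 against 6.79 FPKM). Dissociation stress genes had a median of 0.30 (percentile 99.9; Fosb 1114 against 575 FPKM) and ribosomal protein genes 0.24 (percentile 99.8). With a pseudocount of 10 FPKM in place of 1, the medians fell to 0.51 for inflammatory, 0.22 for interferon response, 0.10 for complement and 0.33 for adipocyte genes, and were 0.50 for fibroblast and 0.55 for monocyte genes.

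Basal markers were close between the P4 libraries, with Krt5 at 456 against 436 FPKM and Krt14 at 471 against 561 FPKM, and the basal mammary list had a median of 0.09 (percentile 85.9). Genes of mammary stem cells had a median of 0.04 (percentile 58.9), Wnt10a at 7.12 against 25.3 FPKM and Nrg1 at 42.9 against 17.7 FPKM. The luminal keratin Krt8 had 117 against 72.1 FPKM, and Krt18 157 against 83.0 FPKM. Cxcl12 had 350 FPKM in the knockout and 270 FPKM in the control, and Cxcr4 35.6 against 67.8 FPKM. The 10 highest ratios were those of Mrps21, Hist1h4c, Dnajc15, Snord89, Leap2, Ccdc58, S100a4, LOC100861853, LOC100861902 and Fxc1, and the 10 lowest those of Them5, Snord88c, Upk1b, Hist1h4h, S100a14, Fkbp2, Expi, Ndufa3, Dctpp1 and Hist2h4; Them5 had 0.194 against 24.4 FPKM. At 10 FPKM or more in the higher library, 527 of 6599 genes were at least 2-fold higher and 352 lower, with no replicate and no p. Small noncoding RNA made up 98.9% of the FPKM sum in the control and 97.7% in the knockout.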

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

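The test of the difference between the knockouts was planned; the tests of explanations for the Lyz2 result were chosen after it was seen.

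The change of Lyz2 differed between the Cxcr4 and the Cxcl12 knockout by a log2 value of -6.08, the sole gene that passed that test over all genes. Fewer macrophages in the knockout sort are argued against by the other genes of general macrophage identity, whose median change was 0.15. The standard error of 0.20 is over those genes, not between samples. With Lyz2 included, the median of the list was 0.15 in repeat 1 and 0.21 in repeat 2. Transfer of reads to the neighbouring paralog Lyz1 is argued against too, since Lyz1 gained at most 18.6% of the CPM that Lyz2 lost, and -2.21% in the other repeat. The Cre insertion itself, which in LysM-Cre mice sits in Lyz2, and an effect of Cxcr4 loss on Lyz2 were not separated by a test. The knockout libraries held 1.86% and 0.659% of the Lyz2 of their repeat's control, which by itself favours neither. The labels do not give the genotype of the insertion. Cxcr4 fell less, to 232 and 140 CPM from 819 and 318 CPM in repeats 1 and 2. Lyz2 stood at 5099 and 6678.5 CPM in the Cxcl12 knockout, against 7922 and 7433 CPM in its controls. It stood at 5511 CPM in the CXCR4-negative library. Neither the Cxcl12 knockout nor the sort deletes Cxcr4. Its level was 661 and 483 CPM in the Cxcl12 knockout and 772 CPM in the CXCR4-negative library. Lyz2 in those libraries thus does not test an effect of Cxcr4 loss. The size of the Cxcr4 fall does not set that of Lyz2, so the cause stays open.

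The mitochondrially encoded genes were also singled out because their changes differed between the knockouts, by a median of 0.41 on the log2 scale with the preset correlation; the call ended with an estimated one (adjusted p = 0.940). In repeat 1 their median was higher in the Cxcl12 (0.40) than in the Cxcr4 knockout (0.26). This pattern was not weighed further and no biological explanation was tested.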

How the results depend on the processing

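Quantile normalization (gene counts), the trend, the pseudocount, the filters, the block within a Cre line, the 4-library fits, estimated correlation, fry and leaving out libraries were planned; the common block, the 6 libraries with at most 30% of genes at 0, median-ratio scaling, library weights, voom, shared spread, list scalings and pseudocount, and all but the set sizes for the relations were chosen after seeing the data. The cause was not tested for any change below, except that a higher or lower minimum tests fewer or more genes.

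Genes that passed: without trend 0 for the Cxcr4 knockout, 0 for the difference between knockouts and 0 for the CXCR4 sort; without filter 8, 2 and 0. With the block within each line, the common block or only the 4 libraries of the experiment, 1 gene passed for the Cxcl12 knockout, and with the 4 libraries 2 for the Cxcr4 knockout. Same-numbered samples deviated together only weakly (r across genes 0.139 in the LysM-Cre and 0.091 in the K8-Cre line), and the labels tie them by number alone. Library weights gave 6 for the Cxcr4 knockout and 2 for the difference, voom 7 for the Cxcl12 knockout and 7 for the difference, and shared spread 81 for the CXCR4 sort. Leaving out each of 8 libraries gave 1 to 150 genes for the Cxcr4 knockout, 0 to 151 for the Cxcl12 knockout and 1 to 30 for the difference.

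Lists that passed: 0 in all 4 comparisons with estimated correlation, which had 4 or 1 residual degrees of freedom, and with fry in 1 direction. Fry in either direction passed 5 for the CXCR4 sort and 0 for the others. Quantile normalization gave 0 for the Cxcr4 knockout, 1 for the Cxcl12 knockout and 0 for the difference. The block within each line gave 4 for the Cxcr4 knockout and 4 for the difference, and for the difference the common block gave 3, median-ratio scaling 0, pseudocount 0.1 gave 2 and the 6 libraries 9. Leaving out each library gave 1 to 13, 1 to 8 and 0 to 9.

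Sets of CXCR4-positive genes in the knockouts: the 100 higher genes of smallest p stood at 0.22 for the Cxcr4 and -0.43 for the Cxcl12 knockout, the 300 at -0.37 for the Cxcl12 knockout. With quantile normalization the lower set reversed to 0.075 and 0.14, and the higher set stood at 0.16 and -0.01 in place of 0.08 and -0.25.

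Genes at least 2-fold apart in culture, at 1 CPM or more: 7646 for CXCL12 over untreated, 8296 for inhibitor over untreated, 8617 for both over inhibitor and 9495 for both over CXCL12; at 50 CPM or more 289, 693, 1165 and 1127. The balance of higher and lower genes turned at 1 CPM, with 3994 and 3652 for CXCL12 and 4010 and 4286 for the inhibitor over untreated. For both over inhibitor it was 2872 and 5745 at 1 CPM. For both over CXCL12 it was 2934 and 6561 at 1 CPM, and 606 and 521 at 50 CPM. For the inhibitor with and without CXCL12, r was 0.23 at 50 CPM or more. In P4 cells a pseudocount of 10 FPKM gave 339 genes, a minimum of 1 FPKM 3042 and of 50 FPKM 175.

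Single genes that reversed: Cxcr4 in the CXCR4 sort to 0.047 with median-ratio scaling; Gvin1 to -0.41 and Cxcl12 in the Cxcl12 knockout to -0.61 in the 6 libraries. Leaving out each library gave Gvin1 -0.41 to 5.39, Cxcl12 -2.27 to 0.64 in the Cxcr4 knockout and -0.61 to 2.96 in the Cxcl12 knockout. Lyz2 ranged from -7.41 to -5.53 in the Cxcr4 knockout when each library was left out, and passed each time.

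Of the other values, 631 with a test kept their direction and side of the threshold, 54 kept direction but no longer passed and 31 came to pass. Of those without a test, 814 kept their sign with little change, 5 list medians near 0 changed sign with median-ratio scaling and 42 moved.

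Depth limits genes under 0.0806 to 0.349 CPM. Scaling by total counts was not run, since CPM already is one, and tools for counts need whole counts. Without a CXCR4-positive library no residual degree of freedom is left, and the CXCR4-negative library has no replicate to leave out.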

Other observations

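The list tests and the fits without single libraries were planned; their use as tests of these explanations, both scalings of lists and the fit to 6 libraries were chosen after the results were seen.

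Genes of 8 lists, most of them macrophage lists, were lower against other genes in macrophages of the Cxcl12 knockout with the preset correlation, and none passed with an estimated correlation (adjusted p of 0.629 or above). With quantile normalization 1 of the 8 passed, general macrophage identity, with a median of -0.40 (SE 0.21) against -0.39 (SE 0.28) before. Each SE here is over the genes of a list and does not measure the spread between samples. The other 7 had medians of -0.36 to 0.01 (SE 0.10 to 0.27) against -0.30 to -0.12 (SE 0.09 to 0.30) before. The distance to the median of all genes shrank mostly because that median fell from 0.36 to 0.02: from -0.75 to -0.42 for general macrophage identity, and from between -0.66 and -0.48 to between -0.38 and -0.01 for the other 7. Median-ratio scaling, with the median of all genes at 0.34, left all 8. In the 6 libraries with at most 30% of genes at 0, where that median was 0.03, 6 of the 8 passed, general macrophage identity at -0.55 (SE 0.16). Scaling of libraries that detect different numbers of genes thus cannot be told apart from a change in the cells, since these fits disagree and the last holds 1 K8-Cre control library. The K8-Cre control library with the most genes at 0 cannot be told apart as a cause either: 4 of the 8 lists passed without it, between the bounds set for either reading. Without that library the distance to all genes was -0.58 for general macrophage identity, against -0.75 with it. For resident stromal, CX3CR1 ductal and complement genes it was -0.56, -0.61 and -0.47, against -0.56, -0.66 and -0.55. It shrank to -0.36 for alternative activation, -0.23 for lysosome, -0.06 for dissociation stress and -0.14 for mitochondrially encoded genes. The first 4 distances were thus present without that library, but only 1 K8-Cre control was left. A loss of macrophage identity after luminal Cxcl12 deletion stays open, as untested.

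Macrophage genes were lower, and monocyte and dendritic cell genes higher, in the CXCR4-negative library. A general failure of detection is argued against, because the 6.01% of its genes at 0 lie between the 5.03% and 8.15% of the CXCR4-positive libraries; loss of single genes is not, as 61 genes were under 1 CPM there and above 10 CPM in the others, against 10 and 24 such genes in the positive libraries. Dendritic cells and monocytes among the CXCR4-negative cells cannot be told apart from another state of the macrophages: the median differences of their lists, -0.98 and -1.44, with 13 of 20 and 15 of 19 members highest there, restate the pattern and do not test it. How many dendritic cells or monocytes the gate on F4/80 and CD11b keeps was not tested. Adgre1, which encodes F4/80, had 1041 and 1429 CPM in the positive libraries and 558 CPM in the negative one. Itgam, which encodes CD11b, had 285, 330 and 305 CPM in the same order. In both positive libraries 17 of 20 dendritic and 17 of 19 monocyte genes also reached 1 CPM, 2 and 5 of them are in another list, and the most abundant dendritic genes were Cd209a (67.0, 56.0 and 333 CPM, the negative library last), Cd24a (65.0, 87.5 and 276 CPM), Irf4 (201, 270 and 247 CPM) and Tcf4 (250, 225 and 171 CPM), the last of which ran the other way. The most abundant monocyte genes were Lyz2 (5985, 7367 and 5511 CPM), which was not higher there, Nr4a1 (324, 262 and 778 CPM), Fn1 (342, 234 and 772 CPM) and Ccr2 (490, 449 and 630 CPM). With 1 negative library neither reading was tested in a replicate.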
